A study of Mus musculus with 6 samples.

How the data were processed

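The labels describe ileum of C57BL/6J mice, RNA taken with RNeasy at a RIN of at least 8, amplified with MessageAmp, labelled with Cy5 and hybridised to Phalanx Mouse OneArray slides in 1 colour. The deposited intensity of each of 26423 probes was given per array, and per the file headers it was raw; its values reached below 0, so it had been background-subtracted by the authors, by a method not stated. The deposited p-value was the detection p of each probe on each array, by the authors' software. A deposited spot flag marked the dimmest spots and was not used. The authors' summary table held an intensity per sample on a linear scale, which matched a weighted mean of that sample's own arrays, with no normalization between samples and no centring. Its column medians were 46.6 for GF_preweaned 1, 33.3 for GF_preweaned 2, 97.9 for SPF_preweaned, 46.8 for MPI_preweaned, 46.6 for GF_postweaned and 70.6 for SPF_postweaned. That table served as an alternative.

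From these values, 50 was added to each intensity, the log2 was taken, and the 21 arrays were quantile normalized. The arrays of each sample were then averaged, so that 6 samples entered the models. GF_preweaned 1 joined 3 arrays of each of 2 name prefixes, G1 and G2, which correlated at r between 0.961 and 0.976, with 373 of 12710 probes at least 2-fold apart. A probe was kept where its detection p was under 0.01 on more than 50% of the arrays of at least 1 sample, which left 12710 probes. The brightest probe stood for each gene, which gave 11771 genes, of which 10976 had a name and 795 were unnamed probes. On the arrays, 22533 probes had 1 symbol, 362 several and 3447 none, and no gene was named from a probe with several. Background correction with normexp and an offset of 50 had been written as the main choice and no correction as the alternative. They traded places because the deposited values proved to be corrected already. The other main choices, the gene lists and the rule for named genes were fixed before the data were examined.

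limma (version 3.58.1, R 4.3.3, with jsonlite 2.0.0) fitted a model with a mean per group (1 residual degree of freedom, 2.51 prior degrees of freedom) and an additive model of colonisation and age (2 residual and 3.64 prior degrees of freedom). Moderated tests were two-sided, adjusted with Benjamini-Hochberg over 11771 genes, at a threshold of 0.05. All residual spread came from the GF_preweaned pair or from departures from additivity, and every lone sample was assumed to vary like that pair. The limma p-values measure differences between RNA samples and not animals. Nothing in the labels says that the GF_preweaned samples came from separate animals or how many animals a sample pooled. The number of samples and arrays limits the precision. At unadjusted p under 0.05, 589 of the 11771 genes would be expected by chance in each comparison. Counts by size used an absolute log2 difference of at least 1. Where a gene was not above background in one group, the difference is given as at least so many fold, the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the dim probe's own.

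Array sets A and B were found from the files, by the highest intensity a sample's arrays reached (65471 to 65474 in A, 65489 to 65492 in B). The probes read on one set only were then picked given that split. These probes were undetected on every array of one set, detected on every array of the other and at least 4-fold apart, and 58 of the 64 stood for a gene. Leaving them out of the rule for named genes was decided after the data were seen.

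For each comparison the rule named the 10 genes with the largest positive and the 10 with the largest negative log2 difference among those past the test, filled by size where fewer passed, among genes with a single symbol, above background in a compared group, at least 2-fold apart and farther apart than the GF_preweaned pair. Where GF_preweaned was compared, the lone sample had to lie beyond both GF_preweaned samples. For the change with age of the SPF against GF difference it named 5 each way. Clone names and a few other genes that the rule chose were left out of the text. The lists overlap, with 18 members of adult epithelium, 10 of distal ileum and 8 of proximal small intestine also in other lists. From each of the 33 fixed lists up to 4 members were named, and 12 genes were chosen for naming in any case, of which 10 were measured. Each list's median was set against 10000 random lists of the same size matched on mean expression over 20 bins. Members that passed when adjusted over the list alone had limma p-values adjusted with Benjamini-Hochberg within that list. These counts were not corrected over the 33 lists or the 9 comparisons, and they rest on the same estimate of spread. camera was run with its preset correlation of 0.01 and, as an alternative, with an estimated correlation, and adjusted over the 33 lists of a comparison. With the preset correlation its p-values rest on the spread between genes and not between replicate samples. With an estimated correlation it tests on the residual degrees of freedom, here 1 or 2, so it had little power to call any list. Calls lost there do not show that correlation between genes caused them.

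The scripts were tested on simulated data, drawn around the mean of the real arrays with the prior variance that limma fitted, with about 200 genes changed by known folds. The 5-group model called 0 of the planted genes in each of its 7 comparisons, and the additive model called 23 of 197 for SPF against GF across ages and 24 of 195 for the ages across colonisation states, with 1 false call each. The simulated spread alone put between 1073 and 3473 unchanged genes at least 2-fold apart, so the counts by size may include many genes that this spread alone gives. That spread came from the GF_preweaned pair, which may differ in more than replicate noise. It may thus be too wide, for the simulation and for the tests of the 5-group model. Simulated against observed, genes at least 2-fold apart numbered 2380 and 1953 for SPF against GF after weaning, 2192 and 2397 for the ages within SPF and 1739 and 796 for MPI against GF. They numbered 1777 and 2930 for SPF against GF before weaning, 1770 and 3003 for the ages within GF, 3473 and 4249 for the change with age and 2223 and 3764 for MPI against SPF. For the additive model they numbered 1074 and 1326 across ages and 1073 and 1682 across colonisation states.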

Results

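The series compared the ileum of C57BL/6J mice raised in a germ-free isolator (GF), mice with a conventional microbiota (SPF) and a humanized gnotobiotic animal (MPI, carrying a human-derived microbiota), before and after weaning. Markers of intestinal lymphocytes, antigen presentation and inflammation were higher in the SPF_postweaned sample than in the GF_postweaned and SPF_preweaned samples, by gene-list calls. These calls take genes and not samples as units. All were lost with an estimated correlation, a version with little power at 1 residual degree of freedom. The iron-binding protein gene Meltf and the scavenging-vesicle gene Mamdc4, both bright in suckling epithelium, were bright in GF_preweaned 1 and SPF_preweaned and dim in the other samples, GF_preweaned 2 and MPI_preweaned included. No gene passed the test in any of the 9 comparisons, so the genes below were chosen by size of difference, and the sizes describe these samples.

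The 6 samples fell into 5 groups, and only GF_preweaned had a second sample. Each sample was read on 3 arrays, except GF_preweaned 1 with 6, and the arrays of a sample were averaged into 1 replicate. The arrays fell into 2 sets, A with GF_preweaned 1, GF_preweaned 2 and MPI_preweaned, and B with GF_postweaned, SPF_preweaned and SPF_postweaned. Within set A, GF_preweaned 2 and MPI_preweaned had another version of the probe annotation than GF_preweaned 1, which shared its version with the samples of set B. Samples of the same set correlated across genes at r between 0.871 and 0.981, with 235 to 2397 genes at least 2-fold apart, and samples of different sets at r between 0.751 and 0.881, with 2336 to 4572 such genes (genes are not independent replicates). A total of 64 probes, among them those of the creatine kinase gene Ckmt1 and the fatty acid oxidation gene Cpt2, were undetected on every array of one set and detected on every array of the other. SPF against GF after weaning, the ages within SPF and MPI against GF therefore compared samples within a set. SPF against GF before weaning, the ages within GF, MPI against SPF and the change of the SPF against GF difference with age crossed the sets, and there set and group cannot be told apart. The GF_preweaned pair differed by at least 2-fold at 2377 of 11771 genes (1242 higher and 1135 lower in GF_preweaned 2), and this pair gave the only estimate of spread between samples.

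**Figure D1:**
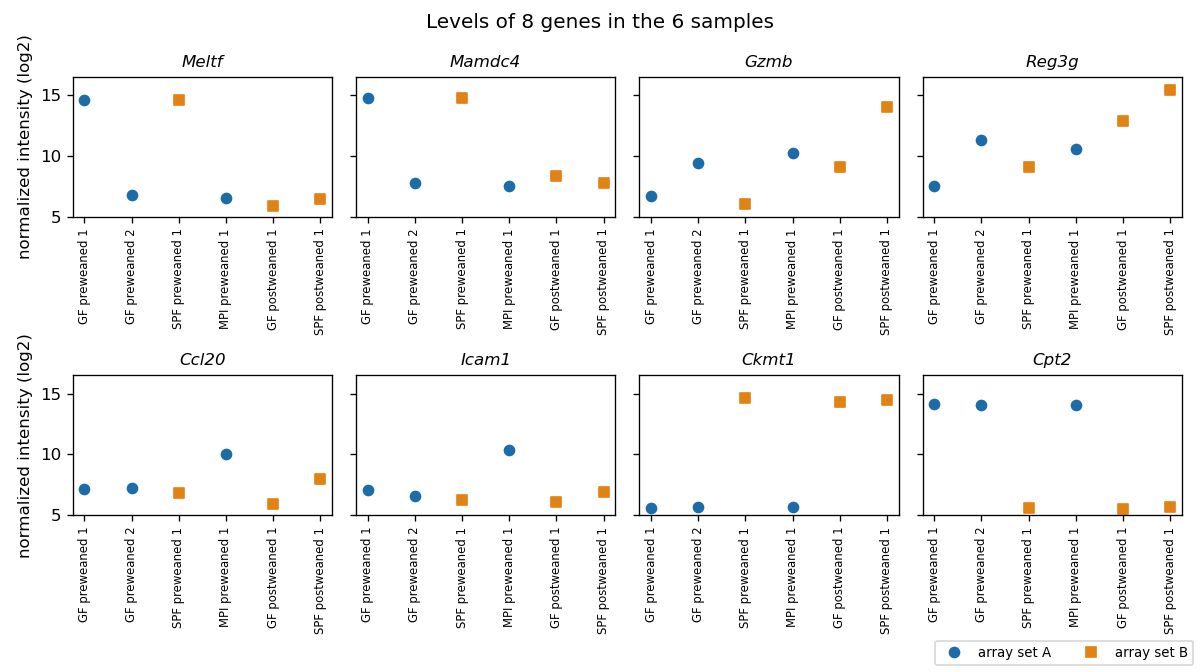
Normalized intensity (log2) of 8 genes in each of the 6 samples, each point the mean of a sample's arrays, with circles for array set A and squares for array set B. Meltf and Mamdc4 lay above 14 only in GF_preweaned 1 and SPF_preweaned, Gzmb and Reg3g were brightest in SPF_postweaned, Ccl20 and Icam1 in MPI_preweaned, and Ckmt1 and Cpt2 followed the array set.

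After weaning, lists of lymphocyte, interferon-response and antigen-presentation genes were called higher in SPF than in GF ileum, though not with an estimated correlation. Killer-cell genes such as Gzmb (a granule protease) and Ccl5 (a T cell chemokine), the ubiquitin-like interferon-gamma target Ubd and the MHC class II genes H2-Aa and Cd74 were all higher in SPF. The list of proximal small intestine genes was also called higher, and the distal ileal and cholesterol synthesis lists were called lower. Both samples came from array set B, so this difference did not cross the sets. Each side was a single sample, so pieces taken from different places along the gut cannot be told apart from an effect of the microbiota.

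limma called 0 of 11771 genes for SPF against GF after weaning (lowest adjusted p = 1.0), with 378 higher and 158 lower at unadjusted p under 0.05. By size, 1178 genes were at least 2-fold higher in SPF and 775 lower, so 60.3% were higher, against 77.7% with each array scaled to the same median and 92.2% in the authors' table, but 48.3% among probes above background in all samples. The pancreatic-type lectin gene Reg1 was higher in SPF by at least 100-fold, Ubd by at least 34.5-fold, the sulfotransferase gene Sult6b2 by at least 23.6-fold, the enteropeptidase gene Tmprss15 by at least 22.4-fold, the relaxin receptor gene Rxfp1 by at least 21.1-fold and the calcium channel gene Trpv6 by at least 10-fold. The vitamin D target S100g was higher by 5.95 (SE 0.94), Gzmb by 4.92, the iron exporter gene Slc40a1 by 4.70 (SE 1.34) and the lymphocyte signalling gene Rgs1 by 4.63 (SE 0.50), all log2 differences. However, Reg1, Sult6b2, Tmprss15, S100g and Slc40a1 were bright in GF_preweaned 2, at 13.53, 12.59, 12.22, 11.92 and 13.39. For them an effect of the microbiota cannot be told apart from a trait of the GF_postweaned sample. Outside SPF_postweaned, Ubd, Rxfp1, Gzmb, Trpv6 and Rgs1 reached at most 9.37, 7.78, 10.23, 8.98 and 8.53. In the other direction, Atp10a was lower in SPF by at least 18.9-fold, Nkx6-1 by at least 12-fold, Mtcp1 by at least 11.4-fold, Mir137 by at least 10.6-fold, Odf1 by at least 8.33-fold and Actrt1 by at least 6.09-fold. Flot2 had a log2 difference of -4.84, the complement gene C3 of -4.00 and Klrg1 of -3.91. For Atp10a, Nkx6-1 and Odf1 the GF_postweaned sample alone was bright, at 11.25, 10.59 and 10.06, against at most 6.35, 6.55 and 6.19 in the other samples. Mir137, Mtcp1, Actrt1, Flot2, C3 and Klrg1 were also brightest there, at 10.42, 10.52, 9.61, 12.03, 11.14 and 10.79. The other samples reached at most 5.77, 6.90, 6.32, 8.21, 8.82 and 7.99. For these genes an effect of the microbiota cannot be told apart from a trait of the GF_postweaned sample. In all, 27 probes were detected on every array of GF_postweaned, at least 4-fold brighter, and undetected on every other array.

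Of the 33 fixed gene lists, camera with its preset correlation called 9 higher and 3 lower in SPF after weaning, and 0 with an estimated correlation. The preset calls weigh genes against genes in 1 sample on each side, so their p-values do not measure spread between samples. The list of T, NK and intraepithelial lymphocyte markers had a median log2 difference of 2.42 over 25 members, 20 of them at least 2-fold higher (adjusted p = 5.06e-18 in camera, adjusted p = 0.785 with an estimated correlation), and 10 members passed when adjusted over the list alone. Its largest members were Gzmb, Ccl5 (4.46), the NK receptor gene Klrd1 (at least 6.05-fold) and the T cell coreceptor gene Cd8a (at least 5.56-fold). The interferon response list had a mean of 1.08, with 17 of 35 members at least 2-fold higher, with Zbp1 higher by at least 3.99-fold, Irf9 by 1.88 and Isg15 by 1.82. Innate inflammation had a median of 0.76, with the chemokine genes Ccl4 and Ccl3 higher by at least 9.17-fold and 5.6-fold and the nitric oxide synthase gene Nos2 by 3.28. Antigen presentation had a median of 0.26 but a mean of 1.10, because the class II genes Cd74 (3.91), H2-Aa (3.87), H2-Eb1 (3.39) and H2-Ab1 (3.12) stood apart from the rest, and these 4 passed when adjusted over the list alone. The antimicrobial and Paneth cell list had a median of 0.76, with Reg4 higher by 2.61 and Reg3g by 2.55. Medians were 0.90 for the proximal small intestine, 0.81 for enteroendocrine cells (Cck 3.51, Ghrl 2.35), 0.72 for myeloid and mast cells and 0.64 for proliferation. The lower lists were distal ileum with a median of -0.80 (the bile acid hormone gene Fgf15 at -2.47 and the cobalamin receptor gene Cubn at -2.17), cholesterol synthesis with -0.67 and goblet cells with -0.40. The lists not called had medians of -0.53 (bile acid and FXR), -0.52 (retinol and vitamin), -0.19 (suckling epithelium), -0.08 (endothelium), -0.08 (fibroblast and matrix), -0.03 (circadian clock), -0.01 (adipose and mesentery), 0.03 (stem cell and crypt), 0.04 (carbohydrate and peptide digestion), 0.06 (lipid absorption), 0.06 (xenobiotic metabolism), 0.08 (mitochondrial respiration), 0.16 (tuft cell), 0.18 (adult epithelium), 0.21 (red blood cell), 0.28 (immediate-early and stress), 0.30 (exocrine pancreas), 0.34 (smooth muscle and enteric neurons), 0.41 (liver) and 0.51 (B and plasma cell). The colon list, with a median of -0.0025, was not called either.

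**Figure D2:**
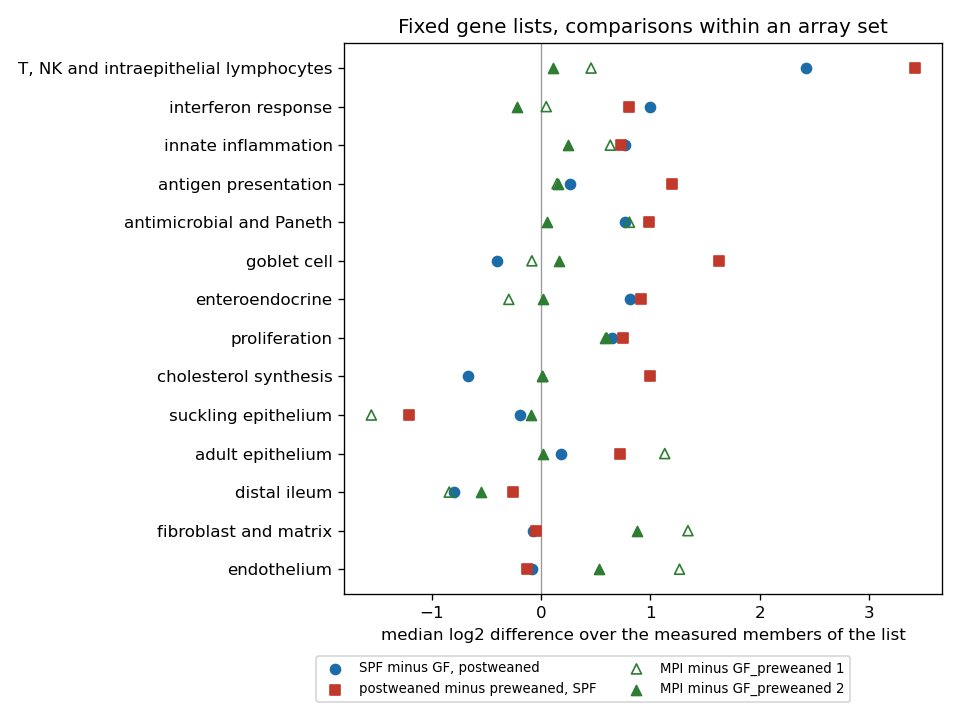
Median log2 difference over the measured members of 14 fixed gene lists in the comparisons within an array set, with MPI shown against each GF_preweaned sample. The lymphocyte list stood highest for SPF against GF after weaning (2.42) and for the ages within SPF (3.42), and the MPI medians depended on which GF sample was the control.

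Between the ages of the SPF mice the lymphocyte, adult epithelium, goblet cell and cholesterol synthesis lists were called higher and the suckling list lower after weaning, though not with an estimated correlation. Genes of the endocytic suckling enterocyte were lower after weaning, among them Meltf, Mamdc4 and the endocytic adaptor gene Dab2. Lymphocyte effector genes, the antibacterial lectin gene Reg3g, the tryptophan-degrading enzyme gene Ido1 and class II antigen presentation genes were higher.

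limma called 0 genes between the ages of the SPF mice (lowest adjusted p = 0.908), with 430 higher and 204 lower after weaning at unadjusted p under 0.05, and 1312 higher and 1085 lower by at least 2-fold (54.7% higher, but 46.2% among probes above background in all samples and 25.2% in the authors' table). After weaning, the granzyme genes Gzma and Gzmb were higher by at least 177-fold and 81.9-fold, Ccl5 by at least 53.2-fold, Rgs1 by at least 44.2-fold, Ubd by at least 39.9-fold, Ido1 by at least 37.3-fold, Tmprss15 by at least 25.8-fold and the carbonic anhydrase gene Car4 by at least 25.4-fold. Reg3g was higher by 6.32 (SE 2.06) and H2-Aa by 5.41 (SE 0.51). Meltf was lower by at least 193-fold, the acyl-CoA thioesterase gene Acot1 by at least 32.3-fold, Podxl by at least 31.4-fold, Rab11fip5 by at least 29.7-fold, Dab2 by at least 18.4-fold and Trpm1 by at least 18.4-fold. Mamdc4 had a log2 difference of -7.04 (SE 3.78), Snx8 of -5.92 (SE 2.34) and Gpx3 of -4.94 (SE 2.13). The GF_preweaned pair, which set the spread, differed at Meltf and Mamdc4 by more than 7 log2 units, so their SE was large. Trpm1 was bright in SPF_preweaned alone.

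camera called 12 lists higher and 2 lower after weaning in SPF, and 0 with an estimated correlation. Lymphocyte markers had a median of 3.42, with 22 of 25 members at least 2-fold higher (adjusted p = 4.73e-25 in camera, adjusted p = 0.768 with an estimated correlation), and 20 passed when adjusted over the list alone. The goblet cell list had a median of 1.62, with the mucus genes Clca1 (2.81), Muc2 (2.81), Agr2 (2.75) and Fcgbp (2.44) largest. Antigen presentation had a median of 1.20 and 4 members past the test when adjusted over the list alone, cholesterol synthesis 0.99 with Sqle higher by at least 6.69-fold, antimicrobial and Paneth 0.99, interferon response 0.80 and innate inflammation 0.73, with Nos2 higher by at least 10.1-fold and 3 members past the test when adjusted over the list alone. Enteroendocrine (0.91), myeloid (0.90), proliferation (0.75), adult epithelium (0.72) and carbohydrate digestion (0.55) were also called higher. The suckling epithelium list had a median of -1.20, with 19 of 34 members at least 2-fold lower, the lysosomal genes Glb1 (-4.33) and Ctsl (-3.96) largest after Dab2, and mitochondrial respiration a median of -0.35.

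The genes most above the GF_preweaned samples in the MPI sample included inflammatory adhesion and chemokine genes. Icam1 and Vcam1, which bind leukocytes to endothelium, and the chemokine genes Ccl2, Ccl20 and Cxcl10 were higher in MPI. The lists of fibroblast, endothelial and smooth muscle genes had higher medians than the inflammation list, and no list call held with an estimated correlation. The distal ileal hormones Pyy and Fgf15 were lower. The apparent gain of drug-metabolizing enzyme genes and loss of suckling genes held against GF_preweaned 1 and nearly vanished against GF_preweaned 2. All of these samples came from array set A, but GF_preweaned 1 had another version of the probe annotation than GF_preweaned 2 and MPI_preweaned.

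limma called 0 genes for MPI against GF (lowest adjusted p = 1.0), with 57 higher and 7 lower at unadjusted p under 0.05, and 501 higher and 295 lower by at least 2-fold (62.9% higher, 74.7% in the authors' table). Taken singly, MPI_preweaned differed by at least 2-fold from GF_preweaned 1 at 2218 genes (1232 higher and 986 lower) and from GF_preweaned 2 at 235 genes (177 higher and 58 lower). Cxcl10 was higher in MPI by at least 5.11-fold, Ccl20 by at least 4.40-fold, the alkaline phosphatase gene Akp3 by at least 3.39-fold, Ccl2 by at least 2.86-fold and Gem by at least 2.24-fold. Icam1 was higher by 3.57 (SE 0.49), though not above background in GF_preweaned 2, Vcam1 by 3.51 (SE 0.84), the mucosal scavenger gene Dmbt1 by 2.75 (SE 0.48) and Rpl8 by 2.63 (SE 0.44). Pyy had a log2 difference of -2.52 (SE 1.03), Ankrd37 of -1.89, Bnip5 of -1.77, Slc34a3 of -1.74, Mtmr11 of -1.49, the fetal growth factor gene Igf2 of -1.47, the neuropeptide gene Nts of -1.45, Dab1 of -1.42 and Ypel2 of -1.41. Idh3g was also lower. All of the lower genes named here stood nearer to GF_preweaned 2 than to GF_preweaned 1, so the sizes depended on the control. Slc34a3, for example, stood at 8.01 in MPI_preweaned, 10.61 in GF_preweaned 1 and 8.90 in GF_preweaned 2, and Igf2 at 10.68, 12.86 and 11.44.

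camera called 12 lists higher and 2 lower in MPI, and 0 with an estimated correlation (lowest adjusted p = 0.805 with an estimated correlation). Fibroblast markers had a median of 1.02 against the pair (1.34 against GF_preweaned 1 and 0.87 against GF_preweaned 2), endothelium 1.02 (1.27 and 0.53), smooth muscle and enteric neurons 1.13 (1.74 and 0.71), myeloid cells 0.75 (0.71 and 0.54) and proliferation 0.64 (0.60 and 0.59). Innate inflammation had a median of 0.38 (0.63 and 0.25), with 15 of 39 members at least 2-fold higher and 3 past the test when adjusted over the list alone. Xenobiotic metabolism had a median of 1.34 (2.26 and 0.14) and carbohydrate digestion 0.64 (1.43 and -0.12). The distal ileum list had a median of -0.61 (-0.84 and -0.55), with Fgf15 lower by at least 7.04-fold than the mean of the pair, which stood at 12.16 and 8.57, and the bile acid binding gene Fabp6 by at least 4.26-fold, with the pair at 7.97 and 11.30. The suckling epithelium list had a median of -0.72 (-1.55 and -0.09).

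Before weaning, the immediate-early and stress list was called higher and the stromal, myeloid, goblet cell and antigen presentation lists lower in SPF than in the GF pair, though not with an estimated correlation. Fosb, Egr1 and Dusp1, which respond to stimuli within minutes, were higher in SPF. The complement genes C1qa, C1qb and C1qc of tissue macrophages were lower. This comparison crossed the array sets, and 17 of the 20 genes with the largest differences were read on one array set only.

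limma called 0 genes for SPF against GF before weaning (lowest adjusted p = 0.247), with 790 higher and 463 lower at unadjusted p under 0.05, and 1571 higher and 1359 lower by at least 2-fold (53.6% higher, 93.0% in the authors' table). The largest differences were Ckmt1 (higher by at least 105-fold), Rn7sk (at least 53.3-fold), Cyb5r3 (at least 36.1-fold), Smdt1 (at least 26.1-fold), Dhrs3 (at least 20.4-fold), Sdf2 (at least 12.2-fold), Atp13a3 (at least 10.3-fold) and Plgrkt (at least 9.39-fold), with the ribosomal RNA gene Rn18s higher by 6.42 (not above background in GF_preweaned 1) and the phosphate carrier gene Slc34a2 by 5.88. In the other direction stood Cpt2 (lower by at least 84.6-fold), Abhd17c (at least 58.3-fold), Map1lc3b (at least 53.1-fold), Nsmce3 (at least 22.9-fold), Pnpla6 (at least 19.6-fold), Pibf1 (at least 17.1-fold), F11r (at least 14.8-fold), C8b (at least 12.7-fold), Thnsl2 (at least 11.4-fold) and Kdm4a (at least 7.74-fold). Without the probes read on one set only, a choice made after the data were seen, the rule added Trpm1 (higher by at least 9.71-fold), Fosb (4.50, not above background in GF_preweaned 1), Egr1 (4.26), Adamdec1 (lower by at least 8.86-fold), H2-Aa (-3.88) and the cholesterol carrier gene Stard4 (-3.71), among others.

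camera called 1 list higher and 7 lower in SPF before weaning, and 0 with an estimated correlation (lowest adjusted p = 0.991 with an estimated correlation). The immediate-early and stress list had a median of 1.46 (2.08 against GF_preweaned 1 and 1.03 against GF_preweaned 2), and 8 members passed when adjusted over the list alone. Dusp1 was higher by 3.70, and the chaperone gene Hspa1a, read on one array set only, by at least 15.9-fold. The lower lists were fibroblast and matrix (-1.53, with 3 members past the test when adjusted over the list alone), myeloid cells (-1.38), endothelium (-1.13, with -0.66 against GF_preweaned 1 and -1.37 against GF_preweaned 2), goblet cells (-1.09), cholesterol synthesis (-0.94, with 1 such member), proliferation (-0.88) and antigen presentation (-0.86, with 3 lower and 1 higher). C1qa had a log2 difference of -3.10, and C1qb and C1qc were lower by at least 2.69-fold and 2.72-fold.

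In GF mice the digestion and goblet cell lists were called higher and the suckling list lower in the older sample, though not with an estimated correlation. The bile acid carrier genes Fabp6 and Slc10a2 were higher after weaning, as was the maltase gene Mgam, but the bile acid list was not called. The lysosomal protease genes Ctsl and Lgmn were lower. Stromal and macrophage markers were lower and immediate-early genes higher, as they were in SPF_preweaned, which shared the array set of GF_postweaned.

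limma called 0 genes between the ages of the GF mice (lowest adjusted p = 0.317), with 499 higher and 424 lower at unadjusted p under 0.05, and 1458 higher and 1545 lower by at least 2-fold (48.6% higher, 34.2% with each array scaled to the same median). GF_postweaned differed by at least 2-fold from GF_preweaned 1 at 4039 genes and from GF_preweaned 2 at 2336. Of the 20 genes with the largest differences 16 were read on one array set only. Among the rest, Iyd was higher after weaning by at least 12-fold, Slc44a4 by at least 7.87-fold and Fam151a by 5.26 (SE 1.92, not above background in GF_preweaned 1), and Slc40a1 had a log2 difference of -5.96 (SE 1.16). The 16 included Ckmt1 (higher by at least 82.6-fold), Cyb5r3 (at least 37.0-fold), Smdt1 (at least 31.4-fold), Plgrkt (at least 22.3-fold), Cpt2 (lower by at least 73.3-fold) and Map1lc3b (at least 46.0-fold), with Sdf2, Fbxo6 and Sec24d also higher and Nsmce3, Pnpla6, F11r, Thnsl2, C8b, Kdm4a and Pibf1 also lower. With those probes left out, the rule added Fabp6 and Reg1, among others. Fabp6 was higher by 6.22 against GF_preweaned 1, where most arrays did not read it above background, and by 2.89 against GF_preweaned 2. Reg1 was lower by at least 13.8-fold than the mean of the pair, which stood at 9.85 and 13.53.

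camera called 5 lists higher and 8 lower after weaning in GF, and 0 with an estimated correlation (lowest adjusted p = 0.691 with an estimated correlation). Carbohydrate and peptide digestion had a median of 1.41 (1.67 against GF_preweaned 1 and 0.40 against GF_preweaned 2), with Mgam higher by 3.06 and the glucose carrier gene Slc5a1 by 2.54. Medians were 1.24 for immediate-early and stress genes, with 3 members past the test when adjusted over the list alone, 0.90 for goblet cells, 0.84 for cholesterol synthesis and 0.55 for lymphocytes (0.84 and 0.39). The suckling list had a median of -1.07 (-1.90 against GF_preweaned 1 and -0.37 against GF_preweaned 2), with Lgmn at -3.29 and Ctsl at -3.27. Liver-type genes (-1.84, with -3.38 against GF_preweaned 1 and -0.84 against GF_preweaned 2), fibroblast and matrix (-1.38), myeloid cells (-1.03), endothelium (-0.89, with -0.47 and -1.13), proliferation (-0.77), enteroendocrine cells (-0.57) and mitochondrial respiration (-0.26) were the other lists called lower.

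The SPF against GF difference was more positive after weaning than before for the lymphocyte, myeloid, antigen presentation, interferon and proliferation lists, and more negative for the immediate-early list, though not with an estimated correlation. Class II genes were lower in SPF than GF before weaning and higher after it, H2-Aa most of all. The before-weaning arm crossed the array sets, so the set enters this contrast fully.

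limma called 0 genes for the change of the SPF against GF difference with age (lowest adjusted p = 0.719), with 458 higher and 311 lower at unadjusted p under 0.05, and 2110 more positive and 2139 more negative by at least 2-fold (49.7% more positive, 32.5% in the authors' table). The rule chose Tmprss15, Cpt2, Sult6b2, Ubd and Map1lc3b as more positive and Ckmt1, Slc44a4, Cyb5r3, Smdt1 and Dhrs3 as more negative. Each of these 10 genes was not above background in at least 1 of the samples compared, so no size is given, and 6 were read on one array set only. H2-Aa, added by the rule without those probes, stood at 7.75 (SE 0.67). camera called 8 lists more positive and 1 more negative, and 0 with an estimated correlation (lowest adjusted p = 0.856 with an estimated correlation). Medians were 2.69 for lymphocytes, 1.69 for myeloid cells, 1.52 for proliferation, 1.45 for fibroblast and matrix, 1.39 for interferon response, 1.31 for enteroendocrine cells, 0.86 for antigen presentation, with 4 members past the test when adjusted over the list alone, and 0.61 for innate inflammation. The immediate-early list had a mean of -1.55.

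Across both ages, the lymphocyte and immediate-early lists were called higher and the cholesterol synthesis, goblet cell, fibroblast and endothelial lists lower in SPF than in GF ileum, though not with an estimated correlation. The lymphocyte list was called higher only after weaning. The immediate-early, fibroblast and endothelial lists were called only before weaning, in the arm that crossed the array sets, and stood at 0.28, -0.08 and -0.08 after it. The T cell receptor chain gene Cd3e and the serotonin synthesis gene Tph1 were higher in SPF, and the matrix gene Dcn and Stard4 were lower. With the set as a term in the model the comparison became the postweaned comparison alone.

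limma called 0 genes for SPF against GF across ages (lowest adjusted p = 0.625), with 680 higher and 176 lower at unadjusted p under 0.05, and 905 higher and 421 lower by at least 2-fold (68.3% higher, 97.0% in the authors' table). Of the 20 genes with the largest differences 14 were read on one array set only, led by Ckmt1 (5.20), Rn7sk (4.75), Cyb5r3 (4.26), Cpt2 (-4.78) and Map1lc3b (-4.46), with Smdt1 and Dhrs3 also higher and Nsmce3, Pnpla6, F11r, C8b, Thnsl2, Pibf1 and Ube2j1 also lower. With the set as a term, Cpt2 stood at 0.18 and Map1lc3b at 0.044, from samples of set B, where neither was detected. The others were Rn18s (4.28, SE 1.20), Reg1, Slc34a2 (4.12, SE 0.98), S100g (3.59, SE 1.02), Ldc1 (3.52, SE 0.81) and Abhd17c (-4.58, SE 1.61). Of the genes with a value in this paragraph, only Slc34a2, S100g and Stard4 were above background on at least 1 array of every GF and SPF sample, so the other sizes are not exact. camera called 4 lists higher and 4 lower, and 0 with an estimated correlation (lowest adjusted p = 0.946 with an estimated correlation). Medians were 0.84 for immediate-early genes, 0.73 for lymphocytes (Cd3e 1.87), 0.56 for the proximal small intestine and 0.37 for innate inflammation, and -1.01 for fibroblast and matrix (Dcn -2.52), -0.93 for goblet cells, -0.83 for cholesterol synthesis (Stard4 -2.54) and -0.82 for endothelium.

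Across both colonisation states, the lymphocyte, goblet cell, cholesterol synthesis and digestion lists were called higher and the suckling list lower after weaning, though not with an estimated correlation. Reg3g, Ido1, Gzma and Car4 were higher after weaning, and Podxl, Acot1 and Gpx3 were lower. These directions held in the ages of the SPF mice, which were compared within an array set but are part of this comparison. With the set as a term in the model the comparison became that of the SPF ages alone.

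limma called 0 genes between the ages across colonisation states (lowest adjusted p = 0.725), with 415 higher and 348 lower at unadjusted p under 0.05, and 887 higher and 795 lower by at least 2-fold (52.7% higher, but 39.3% with each array scaled to the same median and 31.7% in the authors' table). Without GF_preweaned 2 limma called 212 genes, 91 higher and 121 lower. After weaning Fam151a was higher by 4.96 (SE 1.18), Ido1 by 4.93 (SE 1.09), Reg3g by 4.66 (SE 1.25), Gzma by 4.63 (SE 1.45), Map3k6 by 4.49 (SE 0.80) and Car4 by 4.19 (SE 1.03). Podxl stood at -4.74 (SE 0.67), Acot1 at -4.64 (SE 1.19), Gpx3 at -4.63 (SE 1.14), Dpp7 at -4.42, Clic6 at -4.00 and Slc40a1 at -3.89. Of the 20 genes 7 were read on one array set only, Ckmt1 (4.85), Plgrkt (4.46), Cyb5r3 (4.29), Smdt1 (4.16), Cpt2 (-4.84), Map1lc3b (-4.43) and Nsmce3 (-3.71). These 7 and Fam151a, Ido1, Gzma, Map3k6, Car4, Podxl, Acot1 and Sqle were not above background in at least 1 GF or SPF sample, so their sizes are not exact. camera called 9 lists higher and 7 lower, and 0 with an estimated correlation (lowest adjusted p = 0.576 with an estimated correlation). Lymphocytes had a median of 2.02, goblet cells 1.40 with 9 of 14 members past the test when adjusted over the list alone (Fcgbp 2.41, Muc2 2.29), adult epithelium 1.20, cholesterol synthesis 1.15 with 6 such members (Sqle 2.77), immediate-early genes 1.10, carbohydrate digestion 1.03, xenobiotic metabolism 0.57, B and plasma cells 0.49 and innate inflammation 0.18. The lower lists were liver (-1.20), suckling epithelium (-1.11, with 20 of 34 members at least 2-fold lower), fibroblast and matrix (-0.81), red blood cell (-0.67), endothelium (-0.58), mitochondrial respiration (-0.44) and lipid absorption (-0.08, with a mean of -0.56).

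Between the colonised samples before weaning, the stromal, myeloid and antigen presentation lists were called higher and the immediate-early list lower in MPI than in SPF, though not with an estimated correlation. Smooth muscle myosin Myh11 and Vcam1 were higher in MPI. Meltf, Mamdc4 and Fabp6 were lower in MPI. The comparison crossed the array sets and had 1 sample on each side.

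limma called 0 genes for MPI against SPF (lowest adjusted p = 0.396), with 574 higher and 713 lower at unadjusted p under 0.05, and 1804 higher and 1960 lower by at least 2-fold (47.9% higher, 15.5% in the authors' table). Of the 20 genes with the largest differences 10 were read on one array set only, Cpt2 (higher by at least 83.9-fold) and Ckmt1 (lower by at least 137-fold) among them, with Map1lc3b, Nsmce3, Pnpla6 and F11r also higher and Cyb5r3, Smdt1, Dhrs3 and Rn7sk also lower. Outside them, Abhd17c was higher in MPI by at least 45.2-fold, Tmprss15 by at least 30.1-fold, Myh11 by at least 29.6-fold, Vcam1 by at least 21.0-fold and Gnas by at least 18.1-fold. Meltf was lower by at least 133-fold, Slc34a2 by at least 44.2-fold and Sco2 by at least 38.3-fold, with Mamdc4 at -7.24 (SE 3.78) and Rn18s at -6.67 (SE 1.02). camera called 11 lists higher and 1 lower, and 0 with an estimated correlation (lowest adjusted p = 0.932 with an estimated correlation). Medians were 2.70 for fibroblast and matrix, with 9 members past the test when adjusted over the list alone, 2.04 for myeloid cells, with 6, 1.76 for endothelium, 1.44 for proliferation, 1.26 for goblet cells, 1.11 for smooth muscle and enteric neurons and 0.90 for antigen presentation, and -1.01 for immediate-early genes. The suckling list had a median of -0.87 and missed the threshold (adjusted p = 0.0622 in camera).

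Genes that respond to microbes or weaning and were chosen before the data were examined did not share a common division of the samples. The antibacterial lectin gene Reg3g stood at 7.58 in GF_preweaned 1, 11.33 in GF_preweaned 2, 9.09 in SPF_preweaned, 10.57 in MPI_preweaned, 12.86 in GF_postweaned and 15.42 in SPF_postweaned. Its relative Reg3b stood at 9.41, 13.12, 12.86, 12.35, 14.50 and 15.30 in the same order. The sucrase gene Sis, absent from the suckling gut, stood at 8.99 in GF_preweaned 1 and between 13.01 and 15.24 in the other samples, and the trehalase gene Treh at 9.10 and between 12.92 and 14.69. Against the GF_preweaned pair SPF_preweaned was higher at Sis by 1.01 and at Treh by 1.02, but stood at -1.99 and -1.77 without GF_preweaned 1, and MPI_preweaned was higher at Reg3g by 1.12 but stood at -0.75 without it. The fasting-induced lipase inhibitor gene Angptl4 stood at 8.67 in GF_preweaned 1, 13.17 in GF_preweaned 2, 12.41 in SPF_preweaned, 13.36 in MPI_preweaned, 13.12 in GF_postweaned and 10.75 in SPF_postweaned. The lactase gene Lct lay between 13.73 and 14.93 in all 6 samples. Fabp6 ran from 6.73 in MPI_preweaned to 14.19 in GF_postweaned, and Slc10a2 from 5.82 in GF_preweaned 1 to 9.75 in GF_postweaned. Fgf15 was brightest in GF_preweaned 1 (12.16) and dimmest in MPI_preweaned (7.08). The fucosyltransferase gene Fut2 was above background in 1 sample, the oxidase gene Duox2 in 0, and no probe named the acute-phase gene Saa1 alone.

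The sign of a list's median and of its camera direction differed in 3 of 33 lists for SPF against GF after weaning, 3 for the ages within SPF, 7 for MPI against GF, 4 for SPF against GF before weaning, 0 for the ages within GF, 2 for the change with age, 4 across ages, 1 across colonisation states and 2 for MPI against SPF. Median and mean differed in sign in 4, 4, 6, 3, 0, 3, 4, 2 and 7 lists in the same order.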

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

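The camera and limma tests of the fixed lists and of the change with age were planned, and the other tests in this part were chosen after the results were seen. The SPF against GF difference of the proliferation list moved by a median of 1.519 between the ages, from -0.932 against GF_preweaned 1 and -0.840 against GF_preweaned 2 before weaning to 0.645 after it (adjusted p = 1.69e-06 in camera, adjusted p = 0.856 with an estimated correlation). The myeloid and mast cell list moved by 1.692, from -1.404 and -1.407 to 0.720 (adjusted p = 5.11e-07 in camera, adjusted p = 0.856 with an estimated correlation). For both lists the direction of the difference turned with age, which is why they are given here. The difference before weaning crossed the array sets, and limma called 0 genes for the change itself, with 769 at unadjusted p under 0.05.

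The GF_preweaned samples, which the labels treat alike, lay 2377 genes apart by at least 2-fold. Other scalings left at least 2374 such genes, and taking GF_preweaned 1 from the arrays of either name prefix left at least 2320, which argues against scaling or the joined prefixes as the source. Genes that moved the same way in this pair and between the ages of the SPF mice numbered 715, against 243 for independent lists, a ratio of 2.942, and those that moved opposite ways numbered 150 against 241. GF_preweaned 2 may therefore have been taken at a later stage of gut maturation, and the design text does mention a 3-week-old GF mouse. However, GF_preweaned 2 shared its version of the probe annotation with MPI_preweaned and not with GF_preweaned 1. Separate processing of the pair, a mislabelled sample or a differently handled one was not tested and stays open. If the pair differed in stage, any comparison against the GF_preweaned mean mixes stages.

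A group of 64 probes was read on one array set and not on the other. At 9 of the genes 11 other probes were above background, and these differed between the sets by a median of 0.2873, against 4.13 at the probes themselves. Only 1 of the 11 differed in the same direction by at least 50% as much, which argues against a difference of the genes, though 3 were at least 2-fold apart in that direction. The values are consistent with a property of the arrays, such as a changed probe on a later slide lot, though neither files nor labels name a lot. The test reached 9 genes only, and for others among the 64, such as the matrix genes Col4a1 and Sparc and the chaperone gene Hspa1a, a difference of the genes stays open.

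Against GF_preweaned 2, its nearest sample, MPI_preweaned was higher at inflammatory, fibroblast, endothelial and smooth muscle genes. More of the deeper gut wall in the MPI piece could raise these together: in GF_preweaned 2 against GF_preweaned 1 the inflammation list also had a higher median, 0.2141, against 0.25 in MPI_preweaned minus GF_preweaned 2. Vcam1 was also higher in that pair, by 1.59. Icam1 was not, at 7.10 in GF_preweaned 1 and 6.55, not above background, in GF_preweaned 2. Ccl2, Cxcl10 and Ccl20 were not above background in either GF_preweaned sample and cannot decide, so the question stays open. A piece from nearer the stomach cannot be told apart from an effect of the microbiota, since proximal markers lay at percentile 90.085 of matched lists, below the threshold set for that explanation and above the middle. The microbiota of the MPI animal stays among the open explanations, with 1 sample to test it.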

How the results depend on the processing

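The alternatives with a floor at 50, the authors' table after quantile normalization, single name prefixes, the array set as a term and without the probes read on one set only were chosen after seeing the data; the others were fixed before, though normexp and no background correction traded places as main choice. No paired analysis was possible because every group but GF_preweaned had 1 sample. In the simulation the model of group means called 0 of the planted genes, so its 0 calls under alternatives say little about stability. Of 112 limma tests under alternatives, 111 called 0 genes, and a test without 1 GF_preweaned sample could not be run in the model of group means, which then has no residual degrees of freedom. The exception was the ages across colonisation states, where leaving out each GF_preweaned sample gave 0 to 212 genes (212 without GF_preweaned replicate 2, lowest adjusted p = 1.49e-05); the cause was not tested. An intensity trend called 0, with lowest adjusted p between 0.0868 and 0.933.

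Of 120 counts by size, 106 stayed within 1.5 times. With probes above background in all samples fewer genes were tested (5843), which lowered the counts in the order of the design to 1068, 729, 305, 1256, 1193, 1817, 310, 679 and 1381. The authors' table, which is not normalized between samples, gave 5226 genes (4859 higher, 367 lower) for SPF against GF before weaning, 3106 (2865 higher, 241 lower) after and 3501 (3395 higher, 106 lower) across ages, and it put the median of all genes at 0.80, 0.50 and 0.65. MPI against GF ran from 235 genes without GF_preweaned replicate 1 to 2218 without replicate 2.

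Scaling to the same median raised the percent of genes at least 2-fold apart that were higher from 60.3% to 77.7% for SPF against GF after weaning and lowered it from 48.6% to 34.2% for the ages within GF, with medians of all genes at 0.18 and -0.13. Of the 106 camera calls, 96 were kept under that scaling, 100 with the authors' table, 106 without the probes read on one set only and 0 with an estimated correlation, and 0 turned. The version with an estimated correlation had only 1 or 2 residual degrees of freedom, so its 0 calls were nearly fixed by the design.

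Of named gene values 55 changed sign, 26 of them at least 2-fold in the main setting; the cause was not tested apart from the array set. Leaving out each GF_preweaned sample gave, for SPF against GF before weaning, Reg3b -0.26 to 3.45, Angptl4 -0.76 to 3.74, Sis -1.99 to 4.02, Treh -1.77 to 3.81, Slc10a2 -2.72 to 0.26 (not above background in SPF_preweaned and GF_preweaned 1, so its turn carries no weight) and Fgf15 -0.63 to 2.96. For MPI against GF it gave Reg3g -0.75 to 2.99, Reg3b -0.77 to 2.94 and Treh -0.35 to 5.23. Most arrays of GF_preweaned 1 did not read Reg3g above background, so its upper value is not exact. For the ages within GF it gave Angptl4 -0.054 to 4.45, Sis -1.53 to 4.48 and Treh -1.25 to 4.34, and across colonisation states Sis -0.11 to 2.90 and Treh -0.26 to 2.53. With the array set as a term, genes read on one set only turned: SPF against GF across ages gave Smdt1 -0.18, Dhrs3 -0.36, Cpt2 0.18, Map1lc3b 0.044, Nsmce3 0.061, Pnpla6 0.13, C8b 0.033 and Thnsl2 0.11, and the ages gave Ckmt1 -0.21, Cpt2 0.12, Map1lc3b 0.076 and Nsmce3 0.11. These values came from samples of set B alone. Cpt2, Map1lc3b, Nsmce3, Pnpla6, C8b and Thnsl2 were undetected on every array of that set, so their turn carries no weight.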

Other observations

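The tests in this part were chosen after the values were seen, and so were the genes named. Some genes were higher with a microbiota in separate pairs of samples from different array sets. Between SPF_postweaned and GF_postweaned and between MPI_preweaned and GF_preweaned 2, 53 genes were at least 2-fold higher in both, against 17.7 for independent lists, a ratio of 2.992, and 17 were lower in both against 3.82. Genes in opposite directions numbered 12 against 17.4. The shared genes were mixed and were not tested for a theme. They included the mucosal scavenger Dmbt1 (3.45 and 2.49) and the proliferation gene Mki67, as well as the chemokine Ccl20, the protease inhibitor Serpina3g and the alkaline phosphatase Akp3, which were not above background in either GF sample. The overlap may reflect a response shared by both kinds of microbiota. However, each pair had 1 sample per side, and variable genes fall into both lists more often than independent ones. The distal ileum list had a lower median in the colonised sample of both pairs, so pieces from different places along the gut are another open explanation.

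Of 238 genes at least 4-fold lower in SPF_postweaned than in SPF_preweaned, 145 were at least 2-fold lower in GF_preweaned 2 than in GF_preweaned 1 and 148 in MPI_preweaned than in GF_preweaned 1, with 10 and 11 higher. Of 329 genes at least 4-fold higher, 121 and 137 were higher. Among all 11771 genes, 1135 and 986 were lower and 1242 and 1232 higher in these differences. Both used GF_preweaned 1, so they are not independent. Between MPI_preweaned and GF_preweaned 2, 4 of the 238 were lower and 17 of the 329 higher.

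Several immediate-early genes were brighter in every sample of array set B than in every sample of set A. Fosb stood at 11.66 in GF_postweaned, 11.96 in SPF_preweaned and 11.53 in SPF_postweaned, against 6.46 in GF_preweaned 1, 8.47 in GF_preweaned 2 and 7.62 in MPI_preweaned. Egr1, Dusp1 and Atf3 divided the samples the same way, as did the ribosomal RNA gene Rn18s. The clock output gene Dbp stood at 9.48 in GF_preweaned 1 and 9.52 in SPF_preweaned and between 12.22 and 12.84 in the other samples.

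Genes that stood at least 8-fold above every other sample numbered 22 in GF_postweaned, 13 in SPF_postweaned, 12 in SPF_preweaned, 6 in GF_preweaned 1, 2 in MPI_preweaned and 0 in GF_preweaned 2. Genes at least 8-fold below every other sample numbered 29 in GF_preweaned 1, 2 in GF_postweaned, 1 in SPF_preweaned and 0 in the rest. The iron exporter gene Slc40a1 was dim in GF_postweaned alone, at 8.60 against 13.31 to 15.73 in the other samples.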
